A study of Mus musculus with 6 samples.

How the data were processed

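RNA was measured from ovarian granulosa cells of immature wild type mice and of mice with a conditional knockout of the protein kinases ERK1 and ERK2. The mice were 23 days old and had received 5 IU of equine chorionic gonadotropin (eCG), which drives follicle growth, 48 h earlier. Cells were taken without human chorionic gonadotropin (hCG) or 2.5 h or 4 h after 5 IU of hCG, which stands in for the ovulatory surge of luteinizing hormone. Per the labels, total RNA was extracted with a column kit and biotin-labelled cRNA was made from 5 ug of it for Affymetrix arrays. There were 6 arrays, 1 for each genotype at each of the 3 times. The labels name no replicates, so no comparison between a pair of arrays has a replicate error or a p-value.

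The deposited table holds 1 intensity per probe set and array. RMA in the affy package made these values, per the submitters' processing notes. Versions were not given in the sources used here. The deposited intensities were whole numbers from 9 to 59425 on a linear scale, with a median of 54 or 55 on every array. Values on the log2 scale had been assumed when the tests were chosen, so log2 of each intensity was taken and the tests stayed as chosen. Rounding to whole numbers leaves dim probe sets with coarse steps. The quantile step of RMA gives all arrays nearly the same spread of values, so a change in total RNA per cell cannot be seen.

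Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation used here, 932 had several and 9211 had none. Symbols were looked up by gene ID in a mouse gene table of assembly GRCm38.p6, where 34754 of the 34958 had an entry and 0 symbols changed. Each gene was represented by the probe set with the highest mean log2 over the 6 arrays among those naming a single gene, which gave 18194 genes. Of these, 11153 had a mean log2 of at least 6 (intensity 64). That floor lies just above the array medians and was taken as the level under which signal and background are hard to tell apart. A fold change against an intensity under 64 is a ratio of measured values that depends on the background. The folds given are those of the representing probe set, and other probe sets of a gene can give smaller ones. Where the brightest of several over the floor differed at least 2-fold, the second did too, the same way, in 48.8% to 66.2% of genes across comparisons. Probe sets for the ERK1 and ERK2 transcripts were not analysed here, so the genotype labels were not checked against the targeted genes.

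All of 9 comparisons between a pair of arrays used a rule of size. A gene counted as different when the values differed at least 2-fold (log2 difference of at least 1) and the brighter array was at log2 6 or more. A response to hCG was called blunted in a genotype when its log2 size was smaller by at least 1 than in the genotype in which the gene had been selected. The same share was computed with the genotypes exchanged, because selection in 1 genotype makes the other look weaker. Exact Clopper-Pearson intervals of such shares treat genes as independent, which they are not, and leave out array error.

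Using limma 3.58.1 in R 4.3.3, 3 further tests drew on all 6 arrays and the 11153 genes, with Benjamini-Hochberg adjustment at 0.05. An additive model of time and genotype gave the genotype difference over the 3 times and the hCG response over both genotypes (mean of 2.5 h and 4 h minus 0 h). A model of 4 cells, with 2.5 h and 4 h in the same cell, gave the genotype by hCG interaction. Each model left 2 residual degrees of freedom, to which the prior added 3.99 and 2.97. The residual is the variation of a difference between times or genotypes, so these p-values do not measure the spread between animals. Simulated data with 200 changed genes among 11153 were tested the same way. Of genes changed 2-fold, 0% were recovered in each of the 3 tests. Recovery of 4-fold changes was 99.5% for the genotype difference, 96.5% for the hCG response and 0% for the interaction. At 16-fold it was 100%, 100% and 96.5%. In the simulation each changed gene had a constant effect and normal noise. Differences in the data that vary between times enter the residual, so recovery there can be lower.

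Gene lists were fixed before the data were examined, 32 in all. They covered EGF-like ligands, cumulus expansion and matrix, ovulation regulators, immediate early genes, ERK pathway feedback, cAMP and CREB targets, the C/EBP family, steroidogenesis, cholesterol synthesis, preovulatory granulosa genes, luteal genes, mitosis, DNA replication, cell cycle inhibitors, apoptosis regulators, cytokines and innate immune genes, angiogenic factors, glycolysis and hypoxia, the unfolded protein response, heat shock, and interferon-stimulated genes. Markers of other cell types covered oocytes, theca cells, macrophages and leukocytes, neutrophils, lymphocytes, endothelium, smooth muscle, stromal fibroblasts, surface epithelium and red blood cells, and a list of reference genes was added. Some genes are in several lists. The median log2 difference of the members with a mean over the floor was placed among 10000 random lists of the same size, matched on mean expression in 10 bins. A list outside the central 95% of random lists was said to stand apart, which describes these arrays and is no p-value. In a simulation of lists of 25 genes for the genotype difference at 0 h, 8 of 100 unshifted lists stood apart, and 97 of 100 did at a shift of 0.2 (log2).

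Named genes followed a rule. It put the targeted genes first, which were not analysed here, then the 10 largest differences each way for the genotype comparisons after hCG and for the wild type hCG responses, where all probe sets over the floor had to point the same way, and the 5 largest each way elsewhere. Mecom, Snap25 and Msc had no probe set with a mean over the floor, so agreement was not tested for them. Up to 10 genes each way that passed in a limma test, by adjusted p, and any list member were also named. In the interaction test, where no gene passed, the 3 smallest adjusted p-values each way were named after their values were seen. Clone and predicted gene symbols were counted without being named.

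Alternatives were a 3-fold threshold, no floor or filter, a floor or filter at log2 7, the mean of all probe sets of a gene, leaving out probe sets marked x or s, centring each array on its median, cyclic loess between arrays, a trended prior in limma, dropping a model term, and leaving out the arrays of each time. Use of the 0 h array of the other genotype was added after oocyte markers were seen to differ between the 0 h arrays. It mixes the genotype difference at 0 h into each response. Computation of counts, lists and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The number of arrays limits the precision of every value.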

Results

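The 6 arrays compared granulosa cells of wild type and ERK1/2 knockout ovaries at 0 h, 2.5 h and 4 h after hCG, with 1 array per genotype and time and no replicates. Granulosa cells surround the oocyte and line the follicle, and hCG acts on their luteinizing hormone receptor. ERK1 and ERK2 are the kinases at the end of the MAP kinase cascade. The design asks which transcripts responded to hCG in each genotype and which differed between genotypes before and after it. On each array, 47.2% to 47.6% of probe sets reached the floor of intensity 64. The ratio of 3' to 5' probe sets of Gapdh, a measure of RNA integrity, was 4.79, 3.56 and 4.01 on the wild type arrays at 0 h, 2.5 h and 4 h and 5.21, 3.99 and 4.24 on the knockout arrays.

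Across 11153 genes, which are not independent replicates, the closest arrays were the knockout arrays at 2.5 h and 4 h (Pearson r = 0.986) and the wild type and knockout arrays at 0 h (r = 0.982). The wild type array at 4 h and the knockout array at 0 h were the farthest apart (r = 0.871). Within wild type, r was 0.943 between 0 h and 2.5 h and 0.974 between 2.5 h and 4 h. Within knockout, r between 0 h and 2.5 h was 0.948.

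In wild type cells at 2.5 h, several genes of ovulation stood far above their level at 0 h. Among 5 measured EGF-like ligands, which activate the EGF receptor on neighbouring follicle cells, Ereg (epiregulin) went from an intensity of 35 to 15945, Btc (betacellulin) from 46 to 5768 and Epgn (epigen) from 27 to 1146, while 2 lay below 0 h, among them Hbegf (1.76-fold). Of 14 genes of cumulus expansion and matrix, 8 were at least 2-fold higher and 6 lay below 0 h, 0 of them by 2-fold. The higher genes included Ptgs2, the inducible prostaglandin synthase (431-fold), Tnfaip6, a hyaluronan-linking protein (121-fold), Ptx3 (16.2-fold) and Has2, a hyaluronan synthase (11.2-fold). The log2 difference of Ptgs2 was 8.75 by its brightest probe set and 6.12 by another. Of 14 ovulation regulators, 6 were at least 2-fold higher and 4 lay below 0 h. Pgr, the progesterone receptor, was 179-fold higher and Runx1, a transcription factor, 8.13-fold. For Pgr the log2 difference was 7.48 by the brightest probe set and 4.41 by another. Star, which carries cholesterol into mitochondria, was 48.3-fold higher and Sult1e1, the estrogen sulfotransferase, went from 20 to 10513. Nts (neurotensin) was 258-fold higher, F3 (tissue factor) 86.05-fold and Nmu (neuromedin U) 55.9-fold.

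Signalling genes moved with them in wild type at 2.5 h. Of 24 immediate early genes, 14 were at least 2-fold higher and 0 lower, with Egr2 at 16.2-fold, Klf4 at 14.0-fold, Junb at 13.2-fold, Ier3 at 11.4-fold and Egr1 at 4.54-fold. In the ERK pathway feedback list, 9 of 15 genes were at least 2-fold higher, among them the MAP kinase phosphatases Dusp4 (5.75-fold) and Dusp6 (4.30-fold) and the receptor signalling inhibitor Spry2 (3.50-fold). Of 18 cAMP and CREB targets, 11 were at least 2-fold higher, led by Crem, a transcription factor of the cAMP response (37.7-fold), and the phosphodiesterase Pde4b (8.36-fold). The C/EBP family had 3 of 5 genes at least 2-fold higher, including Cebpa (4.73-fold) and Cebpb (2.38-fold). Medians of the EGF-like ligands (5.41, log2), immediate early genes (1.74), cumulus genes (1.37), ERK feedback (1.28), C/EBP genes (1.25), cAMP targets (1.25), luteal genes (1.07), cytokines (0.80), ovulation regulators (0.61) and endothelial markers (0.51) stood apart from random lists. With no floor, where dim ligands enter, the median of the EGF-like ligands was 0.07. On the lower side, preovulatory granulosa genes (-0.43) and mitosis genes (-0.41, 29 of 29 below 0 h but 0 by 2-fold) did.

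The rule of size gave 407 genes higher and 117 lower in wild type at 2.5 h. Named genes on the lower side were Gpr155 (3.69-fold lower), Myf5, a muscle transcription factor (3.35-fold), Kctd14 (3.11-fold), Rfpl4 (2.92-fold), Alms1 (2.86-fold) and the heat shock gene Hspa1b (2.79-fold). Oocyte markers had a median difference of -0.71 (log2) in the same comparison. The median of all genes over the floor was -0.22, and list medians are placed against random lists for that reason. With cyclic loess the split was 491 higher and 50 lower, and against the knockout 0 h array it was 565 and 640.

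At 4 h in wild type, 632 genes were at least 2-fold higher and 1045 lower than at 0 h. Btc had reached 287-fold, Ptgs2 580-fold, Pgr 306-fold, Epgn 99.9-fold, Sult1e1 an intensity of 18464, and Cxcr4, a chemokine receptor, 69.7-fold. Prkg2, a cGMP-dependent kinase, was 59.7-fold higher, after 2.68-fold at 2.5 h. The immediate early genes were lower at 4 h than at 2.5 h in several cases, with Egr1 at 5596 after 9767, Egr2 at 609 after 1639 and Nr4a1, an orphan nuclear receptor, at 2192 after 6344. ERK feedback genes had 10 of 15 at least 2-fold higher (median 1.71), and Dusp4 and Dusp6 stood at 12.9-fold and 9.28-fold. Angiogenic factors had 5 of 13 at least 2-fold higher, including Efnb2 (8.72-fold) and Vegfc (5.34-fold), and 2 lower (median 0.60).

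Genes of the preovulatory granulosa cell were lower in wild type at 4 h. Of 23, 11 were at least 2-fold lower and 1 higher (median -0.97, log2). Inhbb, a subunit of inhibin and activin, was 8.56-fold lower, the FSH receptor gene Fshr 6.29-fold, Hsd17b1, an estradiol-forming enzyme, 3.71-fold, and Foxo1, a transcription factor, 3.05-fold. The exception was Fzd1, a Wnt receptor, which was 7.91-fold higher. Inhbb had a log2 difference of -3.10 by its brightest probe set and -1.90 by another. Of 29 mitosis genes, 28 were below their level at 0 h, but 3 by at least 2-fold (median -0.51); Ccnb2 was 2.85-fold lower. Both list medians kept their sign with cyclic loess (-0.79 and -0.32). Other named genes on the lower side were Smim10l2a (25.5-fold lower), Gpr155 (17.3-fold), Alms1 (14.9-fold), Insyn2b (12.6-fold), Jakmip3 (11.3-fold), Clec1a (9.65-fold), Tulp2 (9.42-fold), Mro (8.99-fold) and the channel subunit Kcne2 (8.91-fold). Oocyte markers had a median of -0.53. The median of all genes over the floor was -0.21 relative to 0 h, and with cyclic loess the split was 757 higher and 678 lower.

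In knockout cells after hCG, 388 genes were at least 2-fold higher and 427 lower at 2.5 h, and 443 were higher and 550 lower at 4 h. Ereg went from 29 to 7644 at 2.5 h, a 264-fold difference. Crem was 40.6-fold higher, Egln3, a prolyl hydroxylase of the hypoxia pathway, 62.3-fold, Pappa, a protease of IGF-binding proteins, 35.7-fold, and Pgr 27.7-fold. By another probe set over the floor, the log2 difference of Egln3 was 2.08. Ptgfr, the receptor of prostaglandin F2-alpha, went from 40 to 5126 by its brightest probe set, and its least responsive probe set over the floor gave a log2 difference of 1.20. Nr4a1 was 20.9-fold higher at 2.5 h and 21.2-fold at 4 h. The cAMP and CREB list had 7 of 18 genes at least 2-fold higher at 2.5 h (median 0.79), with the phosphodiesterases Pde4d at 20.9-fold and Pde4b at 11.2-fold.

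Several steroidogenic, cholesterol synthesis and luteal genes were at least 2-fold higher after hCG in each genotype. In knockout, 5 of 17 steroidogenesis genes were at least 2-fold higher at 2.5 h and 6 at 4 h (medians 0.48 and 0.53, log2, both standing apart). Cyp17a1, the androgen-forming enzyme, went from 1845 to 14251 and 13997 in knockout, and from 1994 to 2037 and 1399 in wild type. Also in knockout, Fdx1, the electron donor of mitochondrial steroid enzymes, was 5.20-fold and 5.10-fold higher. Cyp11a1, which makes pregnenolone, was 3.67-fold and 4.97-fold higher there. In knockout, all of 18 cholesterol synthesis genes lay above their 0 h level at 4 h, 8 of them by at least 2-fold (median 0.85). Among the 8 were Dhcr7 (6.09-fold), Cyp51 (3.92-fold) and Mvd (3.66-fold). In wild type, cholesterol synthesis had medians of 0.26 and 0.23 at 2.5 h and 4 h, with 4 of 18 genes at least 2-fold higher each time and 10 above and 8 below their 0 h level at 4 h, and steroidogenesis 0.23 and 0.05, with 4 and 5 of 17 at least 2-fold higher and 0 and 3 lower. All but the last stood apart. Luteal genes had a median of 1.27 at 4 h in both genotypes. Cyp11a1 and Fdx1 began lower in knockout, at 2598 and 5891 against 6878 and 9151. In the ERK feedback list, 4 of 15 genes were at least 2-fold higher and 1 lower in knockout at 2.5 h (median 0.24). In wild type, 9 of 15 were higher and 0 lower (median 1.28). Macrophage markers had medians of 0.32 and 0.33 in knockout, which stood apart, and glycolysis genes 0.45 at 2.5 h. Surface epithelium markers stood apart after hCG in both genotypes, with medians of 0.14 and 0.37 in wild type and 0.29 and 0.44 in knockout, where 0 of 8 were at least 2-fold higher.

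Genes at least 2-fold lower in knockout after hCG included Myf5 (8.34-fold at 2.5 h), Gpr155 (6.62-fold), Pramel25 (4.43-fold), Tmprss13 (4.35-fold) and Hbegf, another EGF-like ligand (3.97-fold), and at 4 h Clec1a (8.87-fold), Frzb, a Wnt inhibitor (6.29-fold), and Adhfe1 (5.91-fold). All of 18 oocyte markers were at least 2-fold lower at both times, with medians of -1.25 and -1.45 (log2). Against the wild type 0 h array, the counts in knockout were 320 higher and 272 lower at 2.5 h and 337 higher and 326 lower at 4 h.

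**Figure D1:**
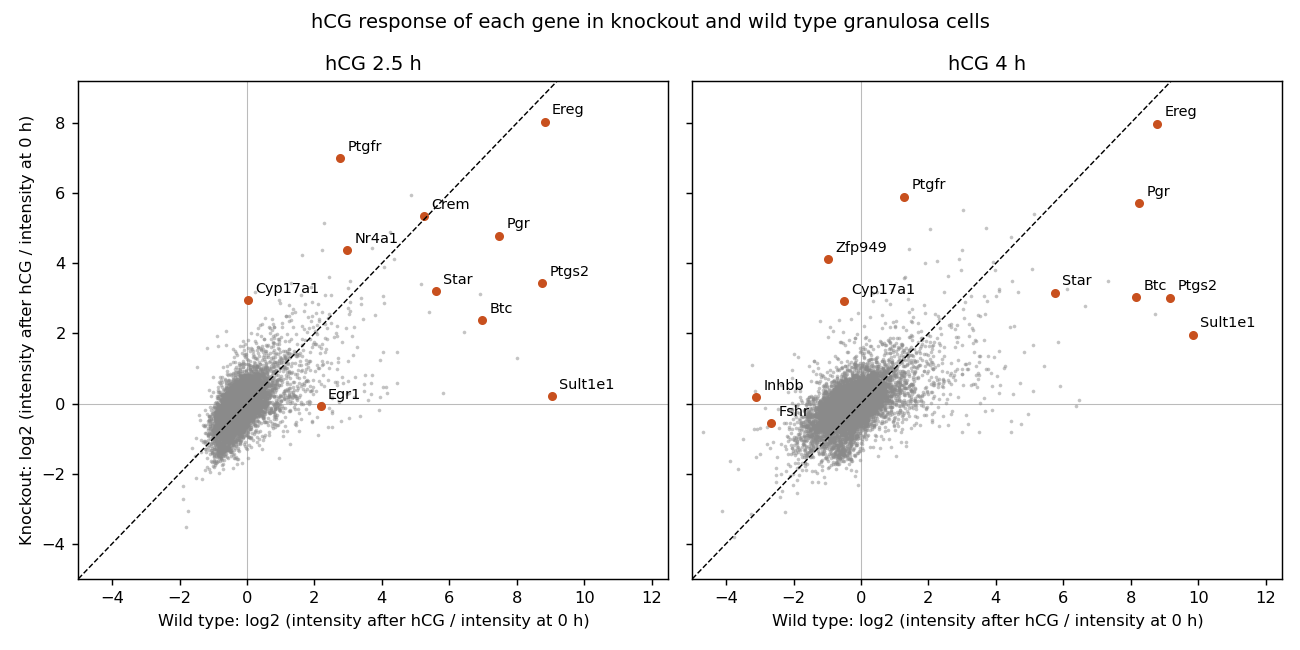
Each point is a gene with a mean over the floor, 11153 in all, with its log2 hCG response in wild type on the horizontal axis and in knockout on the vertical axis at 2.5 h (left) and 4 h (right), from 1 array per genotype and time. The dashed line marks equal responses; Ereg lies near it, Ptgs2, Btc and Sult1e1 lie far below it, and Cyp17a1 lies above it at both times.

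Many wild type responses were smaller in knockout. Of 407 genes at least 2-fold higher in wild type at 2.5 h, 187 had a blunted response in knockout (45.95%, exact 95% interval 41.0% to 50.9%), and 185 were also at least 2-fold higher in knockout. With the genotypes exchanged, 128 of 388 were blunted in wild type (33.0%, 28.3% to 37.9%). At 4 h the shares were 327 of 632 (51.7%, 47.8% to 55.7%) and 140 of 443 (31.6%, 27.3% to 36.2%). Of genes at least 2-fold lower in wild type, 9 of 117 were blunted at 2.5 h (7.69%, 3.58% to 14.1%) and 328 of 1045 at 4 h (31.4%, 28.6% to 34.3%), against 44 of 427 (10.3%) and 82 of 550 (14.9%) with the genotypes exchanged. Only 42 of 117 and 212 of 1045 were also at least 2-fold lower in knockout, against 43 of 427 and 217 of 550 with the genotypes exchanged. A difference near 2-fold counts as blunted only where the other genotype shows almost none. Across genes, the responses of the genotypes had r = 0.616 at 2.5 h and 0.59 at 4 h, with slopes of 0.6 and 0.453 of knockout on wild type. Against the other genotype's 0 h array, the shares of higher genes with a blunted response were 65.66% at 2.5 h and 65.41% at 4 h, and those of lower genes 47.97% and 43.39%. This setting takes each response from the 0 h array of the other genotype. The genotype difference at 0 h thus enters it, and these shares do not measure blunting of the hCG response alone.

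Before hCG, 92 genes were at least 2-fold higher and 103 lower in knockout than in wild type, and of 10092 probe sets without a single gene name, 330 were higher and 16 lower. Several of the lower genes were luteal, signalling or steroid genes. Sfrp4, a secreted Wnt modulator, was 11.1-fold lower, Egr1 7.88-fold, Ptgfr 6.90-fold by its brightest probe set (-0.50, log2, by the least different of 4), Cemip, a hyaluronan-degrading protein, 6.18-fold, Pappa 4.79-fold, Star 4.41-fold, Dusp6 3.62-fold, Egr2 3.61-fold and Cyp11a1 2.65-fold. Luteal genes (median -0.64, 6 of 16 at least 2-fold lower), ERK feedback (-0.57, 2 of 15) and immediate early genes (-0.42, 4 of 24) stood apart from random lists. All of 18 cholesterol synthesis genes (-0.57) and all of 18 glycolysis and hypoxia genes (-0.36) were lower in knockout, 3 and 0 of them by at least 2-fold. Angiogenic factors (-0.42), heat shock genes (-0.36), endothelial markers (-0.35), the unfolded protein response (-0.23) and steroidogenesis (-0.18) also stood apart, and each kept its sign with cyclic loess.

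Higher in knockout at 0 h were Tnfsf11 (RANKL, a cytokine of the TNF family) at 9.42-fold, Nxf3 at 5.21-fold, Khdc1a at 3.59-fold, H3f3b, a histone gene, at 3.36-fold and Nlrp4e at 3.02-fold. The oocyte markers were higher in knockout in 18 of 18 cases (median 0.90, log2), including Bmp15 (2.24-fold), Nlrp5 (1.97-fold), Gdf9 (1.93-fold) and Zp3 (1.88-fold). Surface epithelium markers had a median of 0.34, with Krt7 2.93-fold higher. Interferon-stimulated genes (0.18) and mitosis genes (0.10) stood apart by smaller amounts.

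At 2.5 h after hCG, 169 genes were at least 2-fold higher and 352 lower in knockout than in wild type. Sult1e1 was at 23 against 10513, Nts 102-fold lower, Ptgs2 50.3-fold, F3 49.8-fold, Nmu 46.4-fold, Egr2 42.0-fold, Egr1 37.7-fold, Chst15, a sulfotransferase of proteoglycans, 32.5-fold, Star 23.1-fold and Btc 22.5-fold. Ereg differed by 2.09-fold. Of 5 EGF-like ligands, 4 were at least 2-fold lower (median -1.51, log2), as were 8 of 15 ERK feedback genes (-1.12), 7 of 13 cytokines and innate immune genes (-1), 5 of 13 angiogenic factors (-0.97), 5 of 14 cumulus genes (-0.58), 3 of 18 cholesterol synthesis genes (-0.52), 6 of 14 ovulation regulators (-0.47) and 4 of 16 luteal genes (-0.44). At least 2-fold higher were 2 luteal genes and 0 genes in the other lists of this comparison just named.

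The immediate early genes split at 2.5 h. Of 24, 9 were at least 2-fold lower in knockout and 2 higher (median -0.66). Junb was 12.6-fold lower and Ier3 11.6-fold, while Jun was 2.63-fold and Klf2 2.37-fold higher, and Nr4a1 and Atf3 differed by 1.14-fold each. Of 18 cAMP and CREB targets, 4 were at least 2-fold lower, including the GTPase gene Gem (5.64-fold), and 1 was higher, Pde4d at 2.78-fold (median -0.13). Crem was at 3940 in knockout and 3886 in wild type.

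Higher in knockout at 2.5 h were Svs5 (8.90-fold), Tnfsf11 (8.56-fold), B4galt6 (8.16-fold, and 0.70, log2, by the least different of 3 probe sets), Cyp17a1 (6.996-fold), the clock gene Per2 (6.69-fold), the transcription factor gene Mecom (6.45-fold), Zfp949 (5.89-fold), Marveld2 (5.87-fold), Rasd1, a Ras-like GTPase (5.74-fold), and Nxf3 (4.63-fold). Mecom stood at 258 against 40, with the wild type value under the floor. Preovulatory granulosa genes (median 0.42, 5 of 23 at least 2-fold higher) and mitosis genes (0.50, 28 of 29 above wild type but 0 by 2-fold) stood apart. Endothelial markers were lower (median -0.71), with Cldn5 2.46-fold lower, smooth muscle markers had a median of -0.34, and surface epithelium markers were higher (0.50), as were oocyte markers (0.34, 18 of 18 above wild type). Glycolysis genes stood apart at 0.32, but not with cyclic loess (0.105). The median of all genes over the floor was 0.14. With cyclic loess the split at 2.5 h was 125 higher and 426 lower in knockout, and with the mean of all probe sets 119 and 285.

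At 4 h, 572 genes were at least 2-fold higher and 476 lower in knockout. The split was 360 and 549 with cyclic loess and 333 and 424 with the mean of all probe sets. Lower in knockout were Sult1e1 (78 against 18464), Ptgs2 (90.3-fold), Nmu (84.3-fold), Nts (68.3-fold), Snap25, a protein of vesicle release (53.9-fold), Msc (46.95-fold), Prkg2 (42.2-fold), Gsta2, a glutathione transferase (40.7-fold), F3 (40.4-fold) and Rnd3 (37.0-fold). Snap25 stood at 16 against 862 and Msc at 19 against 892, with the knockout values under the floor. ERK feedback genes had 10 of 15 at least 2-fold lower and 0 higher (median -1.69), with Dusp4 at 23.4-fold and Dusp6 at 8.81-fold. EGF-like ligands (-1.07), angiogenic factors (-0.64), cytokines (-0.64), luteal genes (-0.58), cumulus genes and ovulation regulators (-0.45 each), cAMP targets (-0.23), endothelial markers (-0.22, 9 of 9 below wild type) and immediate early genes (-0.20) stood apart below random lists. Runx1 was 13.0-fold lower, the matrix metalloproteinase inhibitor Timp1 12.7-fold, Efnb2 10.1-fold, the glucose transporter Slc2a1 6.43-fold and the interleukin receptor Il1r1 5.69-fold.

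The preovulatory granulosa genes were the other side of the 4 h comparison. Of 23, 11 were at least 2-fold higher in knockout and 1 lower (median 0.92). Inhbb was 9.08-fold higher, Fshr 5.09-fold, Hsd17b1 4.92-fold, Grem1 3.64-fold, Gata4 3.61-fold, the nuclear receptor gene Nr5a2 3.0-fold and Foxl2 2.77-fold, and Fzd1 was 5.49-fold lower. By another probe set, the log2 difference of Inhbb was 1.82, against 3.18 by the brightest. Mitosis genes were above wild type in 29 of 29 cases, 2 of them by at least 2-fold (median 0.53). Cell cycle inhibitors had a median of 0.64, with 0 of 14 at least 2-fold higher and Gadd45a 4.20-fold lower. Other genes on the higher side were Zfp949 (36.2-fold), Tnfsf11 (34.5-fold), Svs5 (15.1-fold), Kcne2 (13.7-fold), Smim10l2a (11.6-fold), Coasy, an enzyme of coenzyme A synthesis (10.8-fold), Rasd1 (10.7-fold), Cyp17a1 (10.01-fold) and the calcium channel gene Cacna1d (9.80-fold). The Cacna1d value rests on a probe set marked s, and its log2 difference was 0.41 by another. Oocyte markers (-0.02) stood apart below random lists, where the median of all genes over the floor was 0.20.

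**Figure D2:**
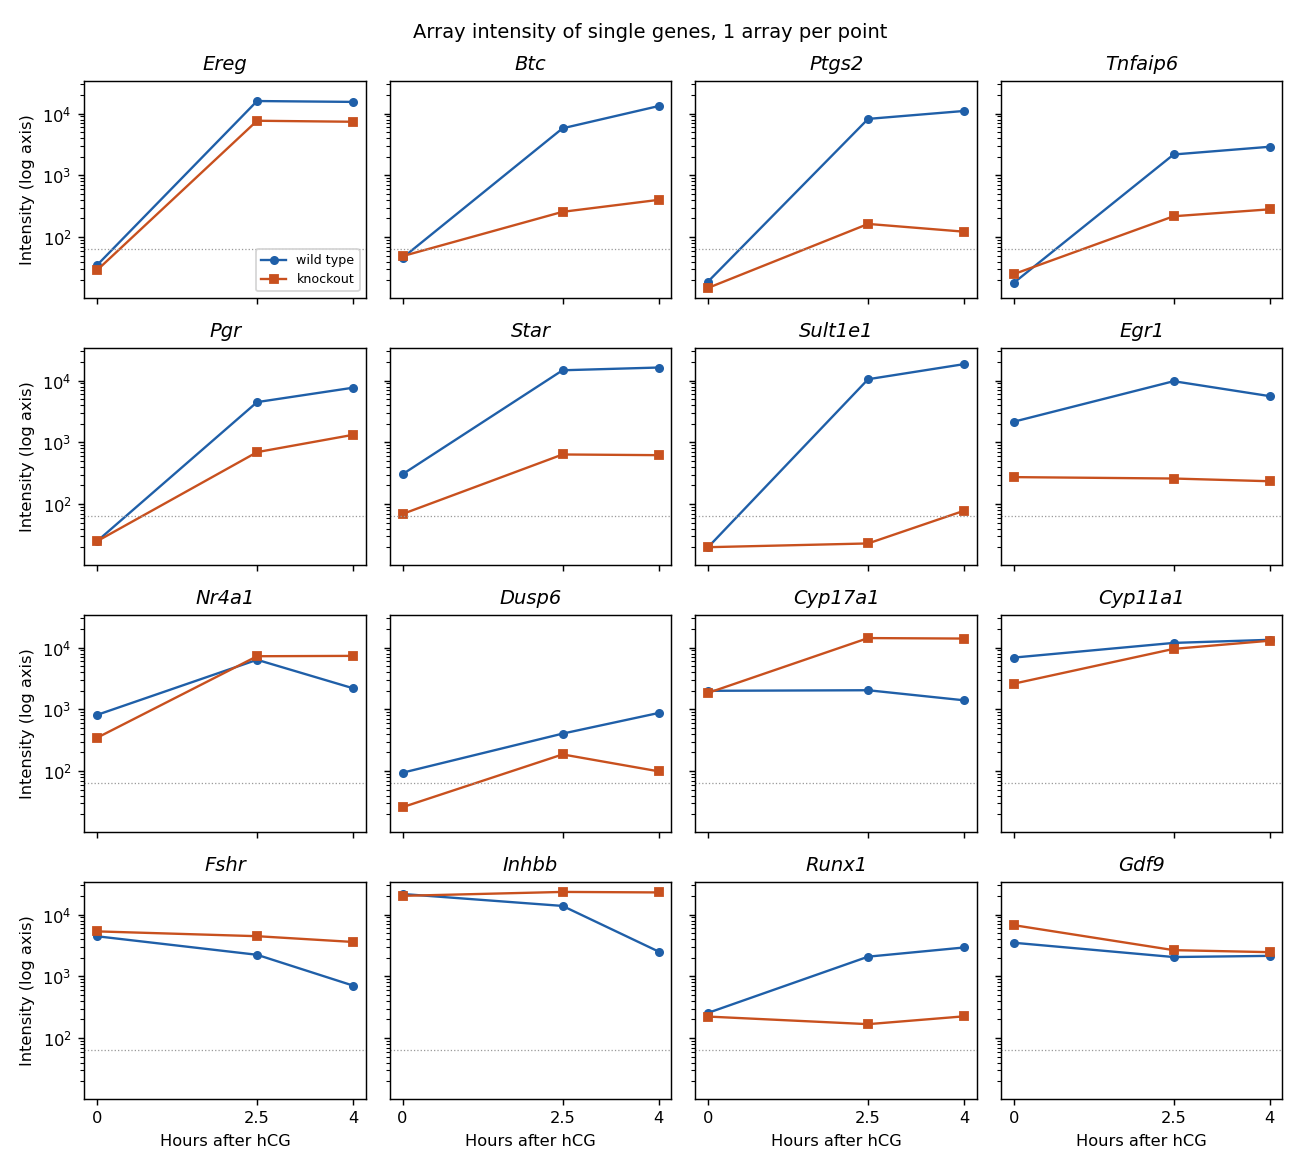
Array intensity (log axis) of 16 list genes at 0 h, 2.5 h and 4 h after hCG in wild type (circles) and knockout (squares), with 1 array per point and the floor of 64 dotted. Ereg stood at 15438 in wild type and 7360 in knockout at 4 h, Ptgs2 reached 11013 in wild type and 122 in knockout at 4 h, and Inhbb stood at 2518 and 22865.

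The genotype differences at 2.5 h and 4 h were partly alike. Of 352 genes at least 2-fold lower in knockout at 2.5 h, 270 were also lower at 4 h, where 15.0 would be shared by independent lists, and 108 of 169 higher genes were shared, where 8.67 would be. As shares of the 4 h lists, these were 270 of 476 lower genes and 108 of 572 higher genes. Of 103 genes lower at 0 h, 53 were lower at 2.5 h and 53 at 4 h, and 15 of 92 higher genes were higher at each later time. In the opposite direction were 4 and 10 of the lower genes at 2.5 h and 4 h, and 2 and 3 of the higher genes. Across genes, the genotype difference at 2.5 h had r = 0.767 with that at 4 h and 0.337 with that at 0 h. From 2.5 h to 4 h, 403 genes moved by at least 2-fold in wild type (184 higher, 219 lower) and 112 in knockout (52 higher, 60 lower).

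Over the 3 times together, limma found 4 genes different between genotypes at an adjusted p under 0.05, and 1940 had an unadjusted p under 0.05. Cemip was lower in knockout (log2 -3.05, SE 0.184, adjusted p = 0.0343), as were Sfrp4 (-2.92, SE 0.203, adjusted p = 0.0389) and Cdc42ep3, an effector of the GTPase CDC42 (-1.81, SE 0.141, adjusted p = 0.0436). Gng13, a G protein subunit, was higher (1.80, SE 0.143, adjusted p = 0.0436). Each of the 4 went the same way at all 3 times. A difference that varied in size between times entered the residual of this test. Adjusted over the list alone, 11 of 15 ERK feedback genes, 8 of 13 angiogenic factors, 6 of 16 luteal genes, 5 of 14 cumulus genes and 5 of 13 cytokines were lower, 11 of 24 immediate early genes were lower and 3 higher, and 4 of 8 surface epithelium markers were higher. No adjustment was made across lists, here and below. Over all genes tested, 1 luteal gene (Sfrp4) passed and 0 in the other lists. The count was 502 without the 0 h arrays, 18 without those at 2.5 h and 273 without those at 4 h, and 0 with cyclic loess or with the mean of all probe sets.

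Between 0 h and the times after hCG, 1135 genes differed over both genotypes in limma, 384 higher and 751 lower after hCG. Ereg rose by 8.41 (log2, SE 0.21, adjusted p = 0.000187), Egln3 by 5.34 (SE 0.241), Crem by 4.64 (SE 0.255), Npr3, a natriuretic peptide receptor, by 4.35 (SE 0.265), Procr, the protein C receptor, by 4.29 (SE 0.159), Camk2n2 by 4.27 (SE 0.183), Slc7a8, an amino acid transporter, by 3.52 (SE 0.158), Mpp7 by 3.10, Tagln2 by 2.82 and the growth inhibitor Btg1 by 2.43. The matrix gene Tnc fell by 2.15 (SE 0.157, adjusted p = 0.00537), Clec1a by 2.28, Rgs13 by 1.84, Frzb by 1.70, Pik3ip1 by 1.66 and the Notch target Hey2 by 1.55. Tex14, Prkd1, Kcnt2 and Txnip also fell, by 1.35 to 1.52.

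By list, 10 of 18 cAMP and CREB targets were higher after hCG over all genes tested and 11 adjusted over the list alone. The corresponding counts were 8 and 14 of 24 immediate early genes, 8 and 11 of 16 luteal genes, 6 and 8 of 14 cumulus genes, 4 and 6 of 17 steroidogenic genes, 4 and 6 of 15 ERK feedback genes, 4 and 5 of 18 cholesterol synthesis genes, and 3 and 3 of 5 EGF-like ligands. In the same lists, 2 and 2 cumulus genes, 2 and 2 steroidogenic genes, 1 and 1 immediate early genes and 1 and 1 EGF-like ligands fell, and 1 ERK feedback gene and 1 luteal gene fell adjusted over the list alone. In the preovulatory granulosa list 3 of 23 fell (5 adjusted over the list alone), among them Foxo1 (-1.13) and the estrogen receptor gene Esr2 (-1.16). Of 18 oocyte markers, 12 fell (18 adjusted over the list alone). How far less oocyte RNA in the preparations after hCG adds to the count of lower genes was not tested. The count was 687 with cyclic loess, which left 363 higher and 324 lower, 701 with the mean of all probe sets, and 165 without genotype in the model.

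The genotype by hCG interaction passed the adjusted threshold for 0 genes in limma, where 1015 had an unadjusted p under 0.05 and the smallest adjusted p was 0.234. In each limma setting tried the count was also 0. The residual of this test is the difference between 2.5 h and 4 h, which includes any real change between them. The single 0 h arrays are assumed to vary alike, so 0 genes does not mean that no interaction exists. Nmu had an interaction of -5.93 (log2, SE 0.439), Ptgs2 of -5.73 (SE 0.394), Palm2 of -2.79 (SE 0.255), Cyp17a1 of 3.18 (SE 0.369), Alas1, the first enzyme of heme synthesis, of 2.18 (SE 0.27) and Trak2 of 1.96 (SE 0.259). Adjusted over the list alone, 4 of 14 cumulus genes, 4 of 14 ovulation regulators, 4 of 15 ERK feedback genes and 3 of 5 EGF-like ligands had a more negative hCG difference in knockout, as did 3 of 24 immediate early genes and 1 gene each of the luteal, cytokine, endothelial and red blood cell lists. Steroidogenesis had 2 genes that way (Star and Sult1e1) and 2 the other way (Cyp17a1 and Fdx1), and cAMP targets 2 (Gem and Avpi1) and 1 (Pde4d). The heat shock genes Hspa1a and Hspa1b, Mvk of cholesterol synthesis and Cyp17a1 in the theca list had a more positive difference. The red blood cell list held 1 measured gene, Alas2, so adjustment over that list changed nothing. No adjustment was made across lists. Fosl1 and Ier3 count in both the immediate early and ERK feedback lists, and Star in both the luteal and steroidogenesis lists.

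**Figure D3:**
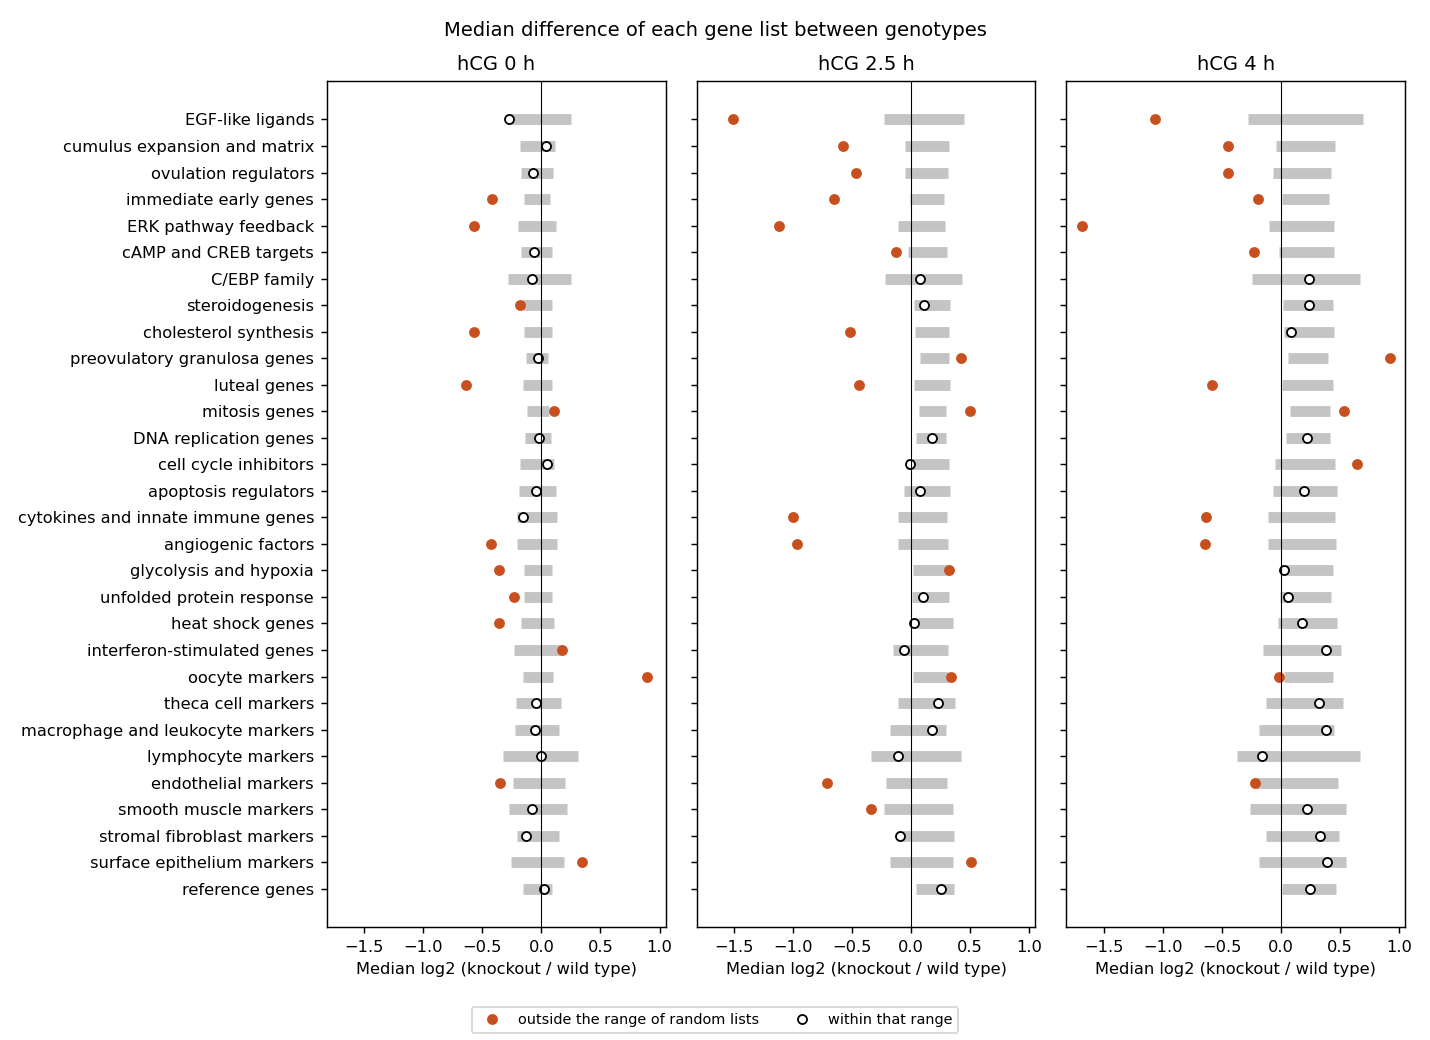
Median log2 difference between knockout and wild type for each gene list with at least 3 measured members at 0 h, 2.5 h and 4 h after hCG. Grey bars span the central 95% of 10000 random lists matched on expression, filled circles lie outside them and open circles within. ERK feedback genes move from -0.57 to -1.12 and -1.69, and preovulatory granulosa genes from -0.03 to 0.42 and 0.92.

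Among the remaining lists, no genotype comparison stood apart for the C/EBP family, DNA replication, apoptosis regulators, theca cell markers, macrophage and leukocyte markers, lymphocyte markers, stromal fibroblast markers or reference genes. The C/EBP family had medians of -0.08, 0.07 and 0.24, and the value at 2.5 h turned negative with cyclic loess. DNA replication genes had medians of -0.02, 0.17 and 0.22 at 0 h, 2.5 h and 4 h, of which the first turned positive with cyclic loess. Apoptosis regulators had -0.05, 0.07 and 0.19, and the later values turned negative with cyclic loess. Within that list, Tnfrsf12a was 4.13-fold lower in knockout at 2.5 h and Bcl2 2.04-fold. Theca markers had medians of -0.04, 0.22 and 0.32, the first of which changed sign with cyclic loess. Aldh1a1 was 4.08-fold higher in knockout at 4 h, and Hhip, a hedgehog inhibitor, 3.99-fold lower. Macrophage markers had -0.05, 0.18 and 0.38, lymphocyte markers -0.01, -0.11 and -0.16, stromal markers -0.13, -0.09 and 0.33, of which the value at 2.5 h stood apart with cyclic loess (-0.26), and reference genes 0.02, 0.26 and 0.25. After hCG, steroidogenesis had medians of 0.11 at 2.5 h, which turned negative with cyclic loess, and 0.24 at 4 h. Cholesterol synthesis at 4 h (0.09), the unfolded protein response (0.10 and 0.06) and glycolysis at 4 h (0.03) all turned negative with cyclic loess. Heat shock genes had 0.02 and 0.18, which did so too and stood apart at 2.5 h (-0.195), and Hspa1b was 3.22-fold higher in knockout at 4 h. Interferon-stimulated genes had -0.06 and 0.38. Of the neutrophil list, 0 genes reached the floor. Of the red blood cell list 1 did, Alas2, which was 2.67-fold lower in knockout at 2.5 h.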

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

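The share without oocyte markers was chosen after the result was seen; the other tests in this part were not.

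The oocyte markers were brighter on the knockout array at 0 h. Scaling of the arrays was argued against, since their median was 0.94 (log2) with cyclic loess and 0.90 without. The share predicted under oocyte RNA in the granulosa preparations was reached. Of the 76 genes at least 2-fold higher in knockout at 0 h (of 92) with a mean over the floor, 78.9% were dimmer on both wild type hCG arrays, as all of 18 oocyte markers were. The share was 78.1% without the 3 oocyte markers among them, 60.5% in genes of like brightness and 31.1% in genes lower in knockout. Genes that fall after hCG for another reason and are higher in knockout would also give a high share. The test therefore cannot single out oocyte RNA. Whether a different number of oocytes per preparation or a difference between the genotypes lies behind the brighter oocyte markers stays open, since each genotype has 1 array at 0 h.

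The knockout arrays at 2.5 h and 4 h were closer to each other than the wild type arrays. The use of 1 RNA sample on both knockout arrays was argued against, since second probe sets shared the sign of the 4 h minus 2.5 h difference in 42 of 43 genes at least 2-fold different by the first (97.7%, 87.7% to 99.9%), 48.8% of them also by 2-fold. For scaling, the wild type count with cyclic loess was 3.54 times the knockout count (396 and 112 genes, against 403 and 112 without). RMA had already given the arrays nearly the same spread, so cyclic loess changed little. It cannot tell whether scaling plays a part. A delayed hCG response in knockout was argued against up to 4 h, since the 187 genes with a blunted rise at 2.5 h were higher at 4 h by a median of 0.126 (bootstrap interval 0.0656 to 0.188), against 0.516 in wild type. The intervals in this paragraph treat genes as independent and leave out array error. The genotype itself stays open, as no biological explanation other than a delay was tested.

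Of 58 genes at least 2-fold different in the same direction at all 3 times, 2 lie among the 50 measured genes on either side of the ERK1 and ERK2 genes, Nupr1 and AI467606. Random windows held a median of 1 such gene and up to 3 at their upper limit. Sequence carried along with the targeted alleles cannot be told apart from an effect of the knockout for these 2 genes, because the count lies between both predictions. The other 56 lie outside those windows.

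For the 4 genes different between genotypes in limma, 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many genes, the real split itself. The highest other split gave 0. With 10 splits the share cannot fall under 0.05, and each other split puts the genotype difference into the residual, so these counts say nothing about chance.

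Gem had responses in opposite directions, with log2 differences of 1.29 and 1.03 in wild type and -1.17 and -1.5 in knockout at 2.5 h and 4 h. Its interaction in limma, which takes both hCG times together, was -2.49 (SE 0.321, adjusted p = 0.343 over all genes), and Gem was among 3 of 18 cAMP and CREB targets that passed adjusted over the list alone. The preovulatory granulosa genes had a median of -0.97 in wild type and 0.0492 in knockout at 4 h, which turned to -0.0359 with cyclic loess. The angiogenic factors had 0.60 and -0.132 at 4 h. Macrophage and leukocyte markers had -0.05 and 0.328 at 4 h, where the wild type value turned to 0.10 with cyclic loess. In these 3 lists, the interaction in limma passed for 0 of 23, 0 of 13 and 0 of 11 genes, over all genes and adjusted over the list alone, and the difference between list medians at 4 h was not tested. Among 10092 probe sets without a single gene name, not counting Affymetrix controls, which the comparisons above leave out, 140 differed at least 2-fold between genotypes at 2.5 h and 247 at 4 h, which was not tested further.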

How the results depend on the processing

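The use of the other genotype's 0 h array was chosen after seeing the data, and it mixes the genotype difference at 0 h into each response. Animals could not be paired because the labels carry no replicate numbers. The genotypes were matched by time only, through the time term of the additive model. Of 440 values of named genes under other settings, 435 kept their direction and size class and 5 moved, 4 with the mean of all probe sets and 1 without x and s probe sets. Of 420 list medians, 406 kept theirs, 13 moved and 1 lost its difference: EGF-like ligands in knockout at 2.5 h had a median of 0 with no floor, where dim members enter, and in wild type 0.0671 at 2.5 h and 0.856 at 4 h. Of 108 counts and shares, 77 stayed within range and 31 moved. At 3-fold the genotype counts were 28, 191 and 382 at 0 h, 2.5 h and 4 h, the wild type hCG counts 230 and 569 and the knockout counts 200 and 267, since a stricter threshold passes fewer genes. The majority changed side at 3-fold for the genotype at 4 h (118 higher, 264 lower) and the wild type response at 4 h (348 and 221). It also did for the knockout responses at 2.5 h (163 and 37) and 4 h (182 and 85). The other 3-fold splits kept their side. With the other 0 h array, the wild type count at 2.5 h was 1205. Blunted shares at 3-fold were 57.78% and 69.83% of higher genes at 2.5 h and 4 h and 0% (of 5 genes) and 48.42% of lower genes. With the other 0 h array they were 65.66%, 65.41%, 47.97% and 43.39%, and the share of lower genes at 4 h was 25.96% with cyclic loess. The genotype test gave 0 genes with no filter, 37 with a filter at log2 7, 8 with a trended prior (eBayes trend), 0 with the mean of all probe sets, 49 median centred, 0 with cyclic loess, 0 with no time factor, and 18 to 502 leaving out the arrays of 1 time. The hCG test gave 432 with no filter, 701 with the mean of all probe sets, 687 with cyclic loess and 165 with no genotype factor. Except where the construction shows it, the cause was not tested. About 47% of probe sets reach the floor, which limits what can be seen of dim transcripts.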

Other observations

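The genes in this part were chosen after their values were seen. In knockout cells, 112 genes were at least 2-fold higher at both hCG times without being so at either time in wild type, against 152 in wild type alone and 145 in both. Alas1, which starts heme synthesis, went from 970 to 7527 and 9192 in knockout and from 973 to 1867 and 1825 in wild type. Cyp11a1 is in the same set, but began at 2598 in knockout and 6878 in wild type and reached 9524 and 12909 against 11901 and 13351. The set also holds Cyp17a1 (log2 2.95 and 2.92), Rasd1 (2.06 and 2.36), Per2 (3.17 and 1.88) and the flow-responsive factor gene Klf2 (1.32 and 2.17). In wild type, Cyp17a1 was at 0.03 and -0.51, Rasd1 at -0.61 and -1.22 and Per2 at 0.25 and -0.18. Klf2 was at 0.845 and 0.862 there, so it also rose in wild type, by less than 2-fold.

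At all 3 times, 46 genes were at least 2-fold lower and 12 higher in knockout. Among the lower ones were the matrix protein gene Sparc (-1.12, -1.53 and -1.22, log2), the protease inhibitor gene Timp1 (-1.06, -2.01 and -3.67) and the protease gene Plau (-1.62, -3.76 and -3.82). The vasodilator gene Adm (-1.20, -1.49 and -1.38), the sterol enzyme gene Hsd17b7 (-1.28, -2.26 and -1.17) and the EGR-binding corepressor gene Nab2 (-1.23, -2.41 and -1.95) were lower too. Among the 12 higher genes were Tnfsf11 (3.24, 3.10 and 5.11), Svs5 (1.25, 3.15 and 3.92) and the keratin gene Krt7 (1.55, 1.57 and 1.29).

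At 0 h, 346 of the 10092 probe sets without a single gene name differed at least 2-fold between genotypes, 330 higher and 16 lower in knockout. Hybridisation controls had median log2 differences of 0.103, 0.259 and 0.13 between knockout and wild type at 0 h, 2.5 h and 4 h.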
